A study of Homo sapiens with 8 samples.

How the data were processed

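SON and IgG CUT&RUN libraries were made from 786-O cells after 3 h of 2 µM PT2399 or DMSO, with 2 libraries in each of the 4 groups, per the labels. The submitters' processing notes name hg19, Bowtie2, Picard, DiffBind and bedtools; their order, versions and settings are not given in the sources used here. Window ends on chromosome 1 fit hg19, and all coordinates are those of the files. The authors deposited 9 tables of 100 kb windows, each shifted by 10 kb, and 9 of 50 kb windows, each shifted by 5 kb. Per the file headers, each holds the log2 mean normalized concentration over both treatments and for each treatment, and the log2 difference of the 2 means. The deposited difference equals DMSO minus PT2399 within rounding, and its sign was turned here so that negative values are lower with PT2399. The authors' p-value and FDR per window were used as deposited, and no test per window was run. How libraries were scaled and whether IgG was subtracted is not given in the sources used here. Many windows share the lowest value of a treatment, -0.05 for DMSO (17334 windows) and -0.40 for PT2399 (2118 windows), and folds against such a value are not given. The authors also deposited 4 lists of merged regions lower with PT2399 and 4 lists of gene symbols, for both window sizes at FDR 0.05 and 0.01, and these hold no value. Merging the windows at FDR under 0.05 gave 344 regions at 100 kb, including all 314 deposited ones exactly; 80 called windows lay outside the deposited regions, all with a PT2399 mean under 2. Read depth is unknown, so no interval that needs it is given.

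The main table was the 100 kb table numbered 1, with lower and higher windows counted at the authors' FDR under 0.05; the other tables and thresholds were alternatives. These choices, the gene lists and the rule for named items were set before the data were examined. The rule took the 10 merged regions with the deepest change among windows inside them that also overlapped a 50 kb region; the 5 largest higher windows after merging; up to 6 members per fixed list in order of FDR; the 15 regions with the lowest FDR that held genes on both FDR 0.01 lists; and VEGFA, CCND1, EPAS1, SON and MALAT1 whatever their value. Without hg19 gene positions the rule asked for the alphabet or the order of the gene list in place of FDR; the order by FDR was used instead through the ties described below, a choice made after the data were seen. Members of the HIF2 target, glycolysis and heat shock lists beyond 6, NEAT1, the S6 kinases, and the examples among the genes of one region were also picked after their values were seen. Some genes and regions that the rule takes are not reported here.

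Gene symbols were matched to a RefSeq table of GRCh38.p14, used only for names and the order of neighbouring genes. Of 2947 names on the main list, 2637 matched directly, 224 by a single synonym and 86 not. The design allowed counts only without hg19 gene positions, so the test of the fixed lists was added after the data were seen. Membership of the lower gene list was shifted along the coding genes of each chromosome (10000 rotations, two-sided), which keeps neighbours together and is called a circular permutation or rotation, and p-values were adjusted by Benjamini-Hochberg over 13 lists. The rotation takes no account of DMSO signal, so it does not separate a list's response from its signal before the drug. Tested on simulated data, the rotation gave p under 0.05 for 3.2% of 500 scattered lists and 2.4% of 500 clustered lists with no effect, and for 100% of 200 lists with 10 of 30 members planted in lower regions. Fisher's exact test gave p under 0.05 for 46.6% of the clustered lists with no effect and was used only as an alternative.

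The files do not pair genes with regions. The main list follows the order of the region file, with chromosome order kept at all 2485 steps between coding names, so coding genes were tied to regions by dynamic programming on that order, on which genes are neighbours, and on presence on the other 3 gene lists. A tie was accepted only if 10 penalty settings gave the same region and the gene was within 5 coding genes of another one of the region; 2441 of 2486 coding names passed. A first version without a limit on gene density and without the neighbour rule was replaced after it packed the genes around GAPDH into an implausibly short region, and its values are kept as an alternative. In 3 simulated lists of 2486 genes, the settings agreed on 2168 to 2265 ties, of which between 96.2% and 98.5% were right. These lists took the number of genes per region from the tie itself and followed its rules of order, and the neighbour rule was not applied. The figure therefore does not measure how many of the real ties are right. A region named with a gene is therefore an inferred tie, and its value is that of the region's lowest-FDR window, not of the gene.

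Alternatives were the other tables and window size, FDR 0.01 and 0.1, adjustment over all 9 tables, removal of the windows of lowest signal, restriction to autosomes, a minimum fold, centring on a median, minimum means, the other gene lists, joined chromosomes and Fisher's exact test. Overlaps of regions used a minimum of 1 bp and a rotation of the 50 kb regions along each chromosome (10000 draws, two-sided). Differences between groups of regions used 100000 permutations, adjusted over all 26 such tests, and left out 7 regions to which no gene was tied in any form. Calculations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9. SON against IgG, replicate blocks, leave-one-out and other normalizations were not run, because the tables give no value per library. Windows at transcription start sites, SON levels of the gene lists and rebuilt gene lists were not run, because no hg19 gene positions were used here.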

Results

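SON CUT&RUN was profiled in 786-O cells, an established line of clear cell renal cell carcinoma that lacks functional VHL and so accumulates the transcription factor HIF-2α. SON is a core protein of nuclear speckles, the nuclear bodies rich in splicing factors, and CUT&RUN releases and sequences the DNA close to the protein that an antibody recognises. Cells were given 2 µM PT2399, an inhibitor of HIF-2α, or DMSO for 3 h, and each treatment was profiled with the SON antibody and with an IgG control, with 2 libraries in each of the 4 groups. The values used were the authors' means per treatment over 100 kb and 50 kb windows of hg19, with their log2 difference, p and FDR; the tables gave no value per library, so no SD, no read depth and no replicate value stands beside any number below. The column headers named the treatment and not the antibody, and no IgG value was given separately. Nothing in the labels said whether the 2 libraries of a group came from separate cultures, so the authors' p-values measured the spread between these libraries, which may be technical. The comparison asks where in the genome the association of chromatin with speckles changes when HIF-2α is inhibited.

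SON signal fell with PT2399 over a set of regions that held FLNA, TGFBI, SLC2A1 and EPHA2. Of the merged regions with genes on both FDR 0.01 lists, the lowest FDR in the authors' deposited tables lay on chromosome X, where the window from 153560001 to 153660000 had log2 means of 11.93 with DMSO and 10.21 with PT2399, a 3.32-fold lower signal (FDR 1.93e-15). The region around it held FLNA, which encodes the actin cross-linker filamin A, together with EMD and RPL10. The region on chromosome 5 tied to TGFBI, a secreted matrix protein gene induced by TGF-β, was also 3.32-fold lower in its lowest-FDR window (135330001 to 135430000, FDR 2.3e-14, the authors' deposited table). The window on chromosome 1 from 43380001 to 43480000, in the region tied to SLC2A1, which encodes the glucose transporter GLUT1, was 3.07-fold lower (FDR 2.4e-12, the authors' deposited table). EPHA2, a receptor tyrosine kinase gene, lay in a region of chromosome 1 whose window from 16430001 to 16530000 was 2.73-fold lower (FDR 2.78e-09, the authors' deposited table). The DMSO means of these windows lay between 11.02 and 11.93. Among the main 100 kb windows, 115 of 123 with a DMSO mean above 11 were lower, so a fall was not particular to these regions.

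**Figure D1:**
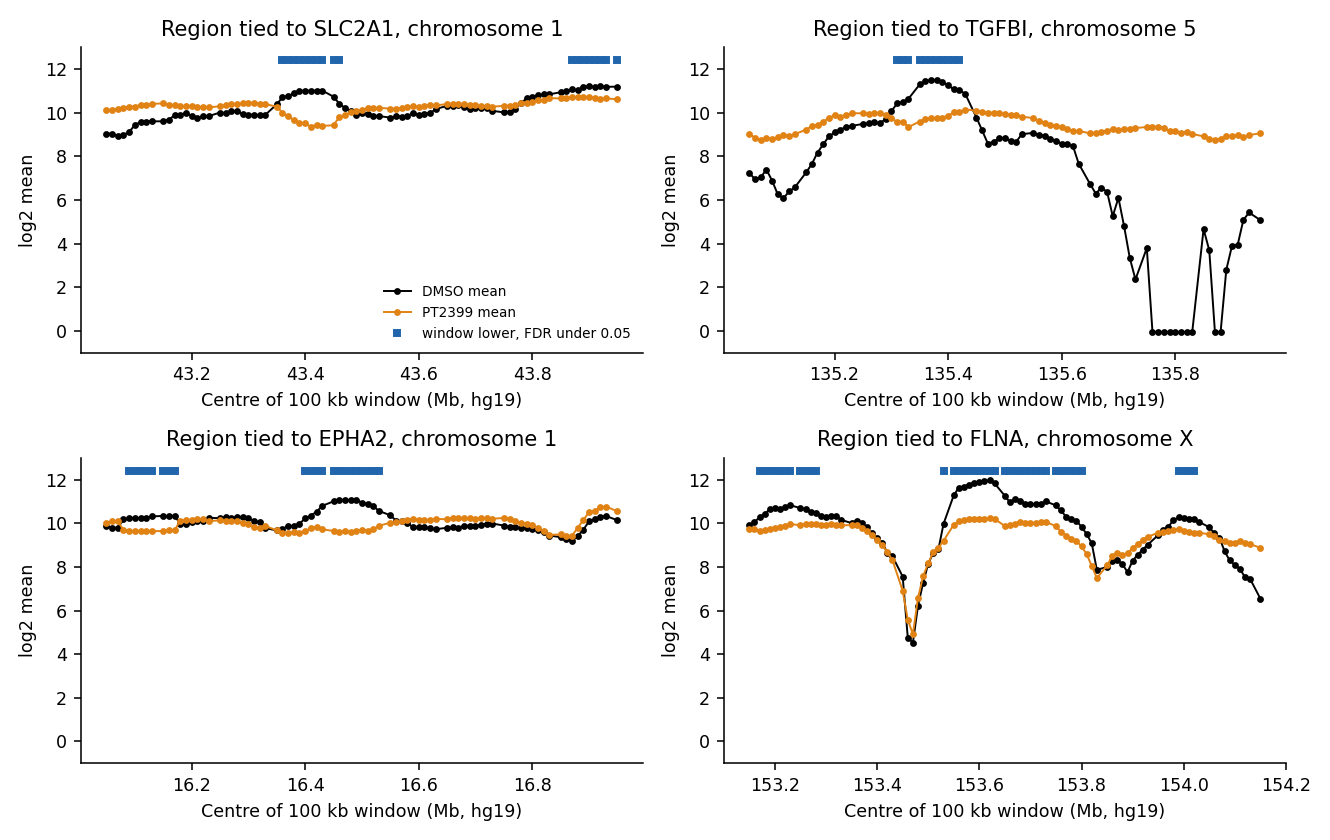
Log2 means of the authors' deposited tables for DMSO (black) and PT2399 (orange) in overlapping 100 kb windows, plotted at the window centre (Mb, hg19) around 4 regions; blue squares mark windows lower with PT2399 at FDR under 0.05. In the lowest-FDR windows the DMSO means are 11.02 at the SLC2A1 region and 11.93 at the FLNA region, and the PT2399 means 9.40 and 10.21. Windows higher with PT2399 at FDR under 0.05 are also present and are not marked. In the SLC2A1 panel that from 43030001 has means of 8.99 with DMSO and 10.24 with PT2399. In the TGFBI panel that from 135720001 has -0.05 and 9.37.

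Other regions among the 15 with the lowest FDR that held genes on both FDR 0.01 lists ranged from a single listed gene to long clusters. On chromosome 11 the region from 64730001 to 66150000 held 51 coding genes found on both FDR 0.01 lists, among them RELA, CFL1, FOSL1 and SART1, and its lowest-FDR window was 2.60-fold lower in the authors' deposited table. In its lowest-FDR window the chromosome 6 region with TUBB, FLOT1 and IER3 was 2.53-fold lower in the authors' deposited table. The chromosome 19 region with PRPF31, CNOT3 and RPS9 was 2.45-fold lower in its own lowest-FDR window in that deposited table. MYH9 and EIF3D lay in a chromosome 22 region whose lowest-FDR window was 2.20-fold lower in the same deposited table. Further regions were represented by BAG6 and the HSPA1A cluster, by RPL13A and IRF3, by ITGA3 and COL1A1, by BSG and STK11, by RPLP0 and PXN, and by AMOTL2. Their lowest-FDR windows were between 1.99-fold and 3.01-fold lower in the authors' deposited table. Across all 314 merged regions the median change of the lowest-FDR window was -0.72 on the log2 scale, with quartiles of -0.99 and -0.54.

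Genes of the fixed HIF2 target list were over-represented among the genes of the lower regions. The list was set beforehand without a stated source, and regulation of its members by HIF-2α in these cells was not tested. Of 47 listed targets, 12 were on the authors' gene list for 100 kb windows at FDR 0.05, against 12.6% of all 19731 coding genes on the chromosomes tested. They included SLC2A1, KISS1R, PFKFB4, RASSF1, POU5F1, DDIT4, BHLHE40, LOXL2, CA9, SCARB1 and SLC7A5. A circular permutation of the lower genes along the coding genes of each chromosome placed 5.27 targets on the list on average (two-sided p = 0.0050, adjusted p = 0.0130 over 13 lists). The call was lost with the chromosomes joined end to end (adjusted p = 0.0582, circular permutation). A gene is named with a region by an inferred tie, since the files do not pair them. The regions tied to PFKFB4, an enzyme gene of glycolytic control, and to DDIT4, an inhibitor of mTORC1, were 2.17-fold and 2.39-fold lower in their lowest-FDR windows in the authors' deposited table, and that of CA9, the carbonic anhydrase used as a marker of VHL loss, was 1.51-fold lower. VEGFA and EPAS1, the HIF-2α gene, were on none of the authors' 4 gene lists, and CCND1 was only on that for 50 kb windows at FDR 0.05.

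Glycolysis had the highest share listed of the 13 fixed groups, 47.4%. Of 19 coding members on the tested chromosomes, 9 were on the list, where the circular permutation placed 2.47 (two-sided p = 0.0004, adjusted p = 0.0026). GAPDH, TPI1 and ENO2 shared 1 region of chromosome 12, whose window from 6960001 to 7060000 was 2.13-fold lower in the authors' deposited table (FDR 5.08e-07), so they are not independent members. SLC16A3, a lactate exporter gene, ALDOA, PFKP, ENO1 and PGAM1 lay in 5 further regions. Their lowest-FDR windows were between 1.55-fold and 2.01-fold lower in the authors' deposited table. The SLC16A3 region spanned 1560 kb, with a median change over called windows of -0.695 on the log2 scale.

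Ribosomal protein genes and heat shock genes were also over-represented. The list rule for ribosomal proteins took 98 coding genes, of which 32 were listed against 13.4 in the circular permutation (two-sided p = 0.0002, the smallest the draws can give; adjusted p = 0.0026). The rule also took 10 S6 kinase genes, which encode protein kinases and no ribosomal protein. Of these RPS6KA4, RPS6KB1 and RPS6KB2 were listed, and without the 10 kinases 29 of 88 members were (circular permutation, p = 0.0002). Besides RPL10 and RPS9, RPS15 lay in a region whose lowest-FDR window was 2.73-fold lower in the authors' deposited table. That of the RPLP0 region was 2.07-fold lower in the same deposited table. The RPS15 region spanned 1100 kb, with a median change over called windows of -0.76 on the log2 scale. Of 18 heat shock genes 7 were listed (circular permutation, adjusted p = 0.0286). HSPA1A, HSPA1B and HSPA1L, which include near-identical copies, lay in 1 region. The call was lost with the FDR 0.01 list (adjusted p = 0.1564, circular permutation) and with the chromosomes joined (adjusted p = 0.0582, circular permutation). The others were HSF1, the main heat shock transcription factor, DNAJB1, HSP90AB1 and HSPB1.

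**Figure D2:**
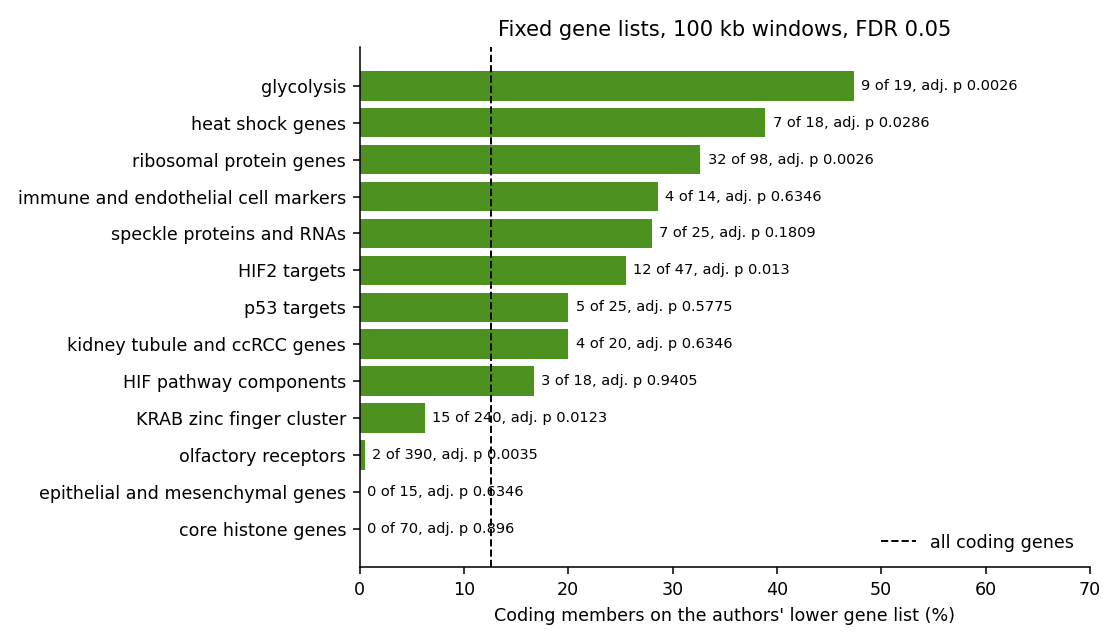
Share of the coding members of each fixed gene list that were on the authors' gene list for 100 kb windows at FDR 0.05 (bars, percent), with counts and the circular permutation (rotation) p adjusted over 13 lists; the dashed line is the share of all coding genes, 12.6%. Glycolysis stands at 47.4% and olfactory receptors at 0.513%.

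Olfactory receptor genes were listed less often than the circular permutation placed them, with 2 of 390 against 56.9 (adjusted p = 0.0035). The 2 were OR1F1 and OR2V2. No lower window had its DMSO mean at the lowest value, where 17334 of 30491 windows stood. The circular permutation was not limited to genes in windows able to fall. This shortfall, and the excess of other lists, were therefore not told apart from differences in DMSO signal. Zinc finger genes of chromosome 19, among them ZNF526 and ZNF628, were listed in 15 of 240 cases against 86.2 in the circular permutation within that chromosome (adjusted p = 0.0123). That call was lost with the chromosomes joined (adjusted p = 0.6965, circular permutation). Components of nuclear speckles did not pass the test, with 7 of 25 coding members listed (circular permutation, adjusted p = 0.1809). They included SRRM2, a scaffold of speckles, SART1, RNPS1 and SRSF2. The non-coding RNAs MALAT1, which concentrates in speckles, and NEAT1, the scaffold of paraspeckles, were on all 4 gene lists. Both lie on chromosome 11, as does SART1. Only coding genes were tied to regions, so these members may share a region and not be independent. SON itself was on none of the 4 gene lists. The 100 kb windows reached only the start of its chromosome, 21, so SON was not testable there. None of the other 6 lists passed (circular permutation, adjusted p between 0.5775 and 0.9405). Members listed were 3 of 18 HIF pathway components (EGLN2, TCEB2 and HSP90AB1), 5 of 25 p53 targets (BAX, BBC3, PLK3, PHLDA3 and TIGAR) and 4 of 20 kidney genes (PAX8, CDH16, SLC34A1 and AXL). The 4 of 14 immune and endothelial markers listed included CD4, CD68 and CD79A, of which CD4 shared the region of GAPDH. No core histone gene of 70 and no epithelial or mesenchymal gene of 15 was listed (circular permutation, adjusted p = 0.8960 and 0.6346).

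The deepest falls, by the largest change inside a merged region, were partly windows in which the PT2399 mean was at its lowest listed value. On chromosome 10 the window from 3770001 to 3870000, in the region tied to KLF6, a zinc finger transcription factor gene, had a DMSO mean of 9.65 while PT2399 was listed at its lowest value, -0.40, in the authors' deposited table. The same held on chromosome 8 from 128840001 to 128940000 with a DMSO mean of 9.32, and the chromosome 1 window from 121480001 to 121580000 had means of 11.79 and 5.04 in that table. No coding gene was tied to either region. In 50 kb windows on chromosome 1 the DMSO mean went from 11.48 at the start 121485001 to -0.05 at 121490001. This fall therefore rests on a short stretch and depends on the placement of the window. In the region tied to BHLHE40, a hypoxia-induced repressor gene, the deepest window fell from 9.71 to 5.80, and in that tied to LOXL2, a lysyl oxidase gene, from 9.62 to 6.96, in the authors' deposited table. The other 5 regions were tied to CTCF, HSD11B2, CD74 with RPS14, MYEOV, and LIF with OSM. Their deepest windows changed by between -2.68 and -2.01 on the log2 scale in the authors' deposited table. The regions tied to CTCF and HSD11B2 are close neighbours on chromosome 16, so the split of genes between them is uncertain.

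Windows higher with PT2399 were far more frequent than lower ones. At FDR under 0.05 in the authors' deposited table, 16756 of 30491 windows were higher and 370 were lower. In 15179 of the higher windows the DMSO mean stood at the lowest value listed, -0.05, so no fold is given for them; the median PT2399 mean of all higher windows was 8.24. The 5 largest after merging, on chromosomes 5, 6 and 18, were all of this kind, with PT2399 means of 10.03 to 11.17, the highest from 58700001 to 58800000 on chromosome 6 beside the centromere. Among 5925 windows with both means of at least 8, 554 were higher and 358 lower, with median changes of 1.07 and -0.64 on the log2 scale. The median change over these 5925 windows was 0.47. With p-values adjusted again over them alone, 247 were lower and 123 higher, and over the windows with both means above their lowest value, 227 and 309. With all changes centred on the median of all windows, a shift of 5.97, 1880 windows were lower and 15242 higher. Centring only gave a new sign to windows already called, because the deposited FDR was not recomputed around the new centre. The sum of the linear means over windows was 2.62 times as large with PT2399 as with DMSO.

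By the authors' FDR, 39 of 43 windows with a mean over both treatments above 11 were lower, and between 6 and 8, 83.9% of windows were higher and 0.0122% lower. These shares describe where the calls lie and test no relation of change to signal, because the change itself helps to set the mean: windows with DMSO at its lowest value and PT2399 near 8 fall between 6 and 8. Across 13142 windows with both means above their lowest value, Spearman's rho of the 2 means was 0.78 and Pearson's r 0.68, as a description across windows, which are not independent replicates.

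**Figure D3:**
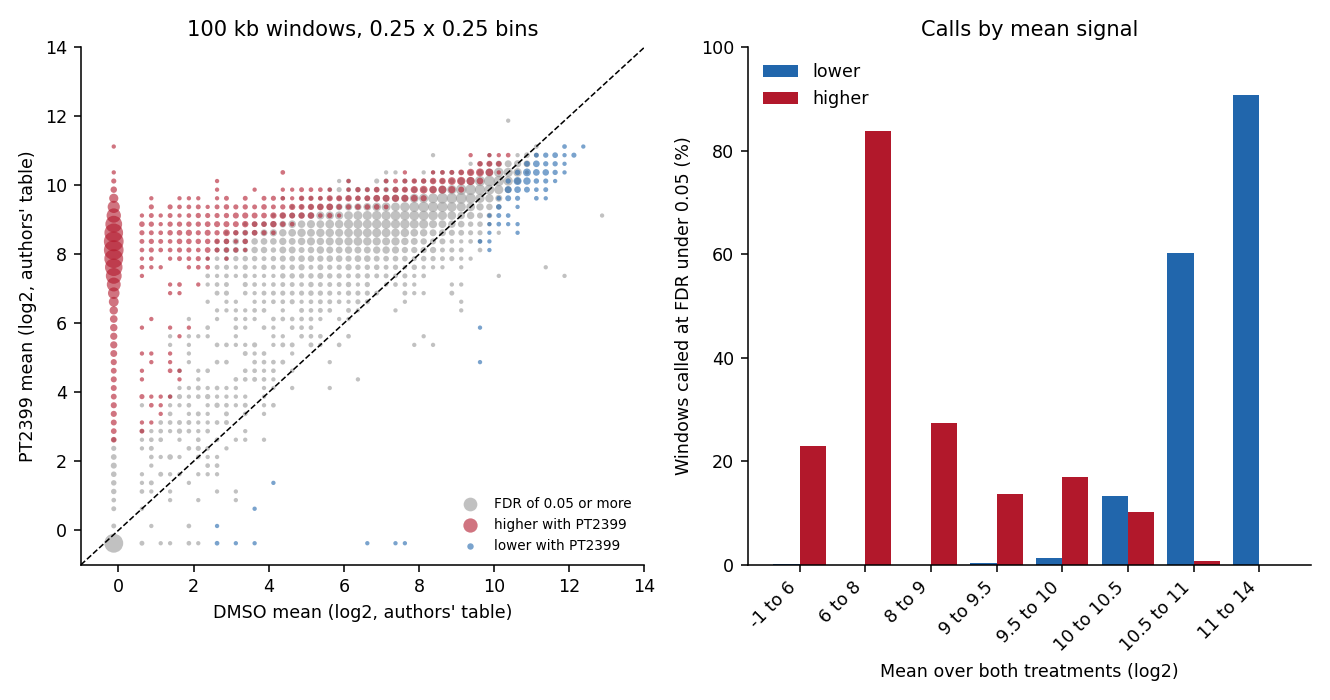
Left, PT2399 against DMSO mean (log2, authors' deposited table) of 100 kb windows in square bins of 0.25, with point size rising with the number of windows and colour by call; the dashed line marks equal means. Right, percent of windows lower (blue) or higher (red) at FDR under 0.05 by mean over both treatments, reaching 90.7% lower above a mean of 11.

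Lower windows were unevenly spread over the chromosomes, which was described and not tested. On chromosome 19, 69 of 590 windows were lower (11.7%), on chromosome 16 48 of 902 (5.32%), on chromosome 17 36 of 811 (4.44%) and on chromosome 22 22 of 512 (4.30%). No lower window had its DMSO mean at the lowest value, where 7.63% of windows lay on chromosome 19 but 73.9% on chromosome 13 and 63.9% on chromosome 18. Over windows above that value the shares were 12.7%, 7.54%, 5.27% and 6.36% on chromosomes 19, 16, 17 and 22. Chromosomes 13 and 18 had 0 lower windows by the DiffBind FDR in the authors' deposited table, 0 at the unadjusted p under 0.05 as well, and 687 and 499 higher ones; over all 9 tables chromosome 18 had 2 lower windows. Chromosome 21 was covered to 4700000 only and was not compared.

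**Figure D4:**
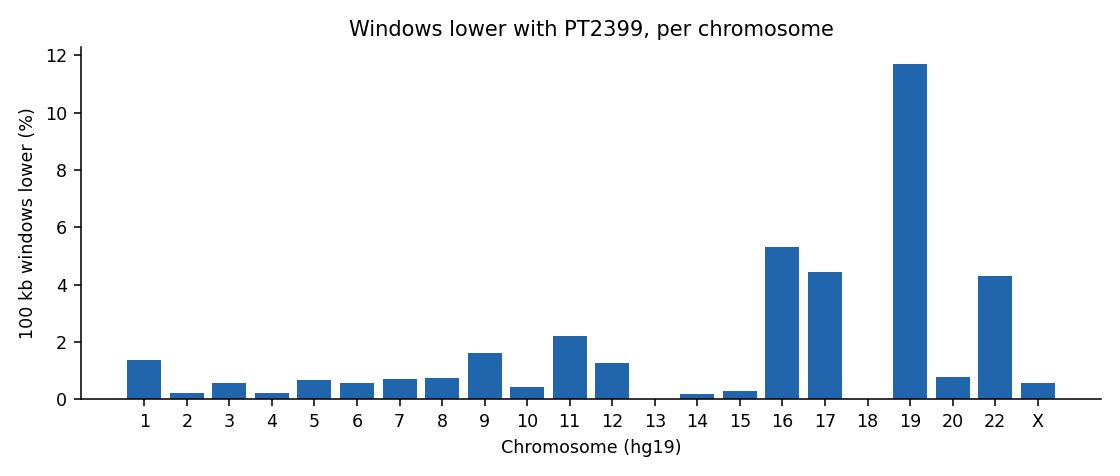
Percent of 100 kb windows lower with PT2399 at FDR under 0.05 (authors' deposited table) for each chromosome of hg19, with chromosome 21 left out. Chromosome 19 stands highest at 11.7%, and chromosomes 13 and 18 at 0.

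Regions lower in 100 kb windows overlapped those from 50 kb windows, which come from the same libraries. The 314 merged regions covered 68.5 Mb, 2.24% of the tested sequence, with a median length of 180 kb. Of these, 311 overlapped a 50 kb region by at least 1 bp, and 396 of 644 regions from 50 kb windows overlapped a 100 kb region, against 53.2 on average in a circular permutation of the regions along each chromosome (two-sided p = 0.0002, the smallest the draws can give). Overlap above random placement was built in, since both sets rest on the same reads in nested windows, so this p is no evidence of repeatability. The gene lists of 2947 and 2982 genes shared 2441. Changes of the 2 window sizes at the same place had a Spearman's rho of 0.95 across windows.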

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

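No paired analysis was possible because the tables give no value per library; for the same reason leaving out a replicate and other normalizations were not run. Tests at transcription start sites or gene bodies, matched random lists, clusters within 500 kb and rebuilt gene lists were not run for want of hg19 gene positions. The list tests, the restrictions on treatment means, the FDR 0.01 comparison of shared genes, the list counts for 50 kb at FDR 0.01, the S6 kinase removal and both versions of the tie were chosen after seeing the data. Over the other 100 kb tables lower windows numbered 375 to 393 and higher ones 16718 to 16819. In the 50 kb tables, which hold more windows, lower windows numbered 735, 724, 729, 737, 752, 735, 768, 755 and 751, and higher ones 32846, 32879, 32887, 32927, 32945, 32870, 32887, 32875 and 32910. A minimum fold at the median of called windows left 1 lower and 8618 higher windows, because the higher folds rest on the DMSO floor. Centring on the median of all windows, a shift of 5.97, gave 1880 lower and 15242 higher. Centring on the windows of highest signal, a shift of 0.715, gave 485 and 16641. Both centrings only gave a new sign to windows already called at the deposited FDR. No window was tested again, so these counts do not show the effect of another normalization. With both means above their lowest value and p adjusted again, 227 windows were lower and 309 higher, and with both means at least 8, 247 and 123, where lower windows outnumbered higher ones. That turn came with the new adjustment, since at the authors' FDR the same windows held 554 higher and 358 lower. The 50 kb list held 644 merged regions, and the FDR 0.01 lists shared 1524 genes, by construction of smaller windows and a stricter threshold. List counts moved at 100 kb and FDR 0.01 for HIF pathway components (1) and zinc finger genes (8). At 50 kb and FDR 0.05 they moved for histone genes (2) and epithelial and mesenchymal genes (1). At 50 kb and FDR 0.01 they moved for HIF pathway components (1), p53 targets (3), olfactory receptors (1), zinc finger genes (4) and epithelial and mesenchymal genes (1). Speckle components moved there from 9 to 5, both counts including the non-coding MALAT1 and NEAT1. The HIF pathway list turned from above to below the rotation mean with the other 3 lists (circular permutation, adjusted p = 1, 0.7979 and 1), and the epithelial and mesenchymal list from below to above it at 50 kb and FDR 0.01 (adjusted p = 1); neither passed in any setting, and the cause was not tested. HIF2 targets had an adjusted p of 0.0234, 0.0172 and 0.0489 with the other 3 gene lists (circular permutation). With the chromosomes joined they lost the call on the main list (0.0582) and at 50 kb with FDR 0.05 (0.0593) and 0.01 (0.0711). They kept it at 100 kb and FDR 0.01 (0.0383). Glycolysis and ribosomal protein genes passed in every setting run. Heat shock genes lost the call with the FDR 0.01 lists at 100 kb and 50 kb (circular permutation, adjusted p = 0.1564 and 0.0628). With the chromosomes joined they lost it on all 4 lists (0.0582, 0.2043, 0.0593 and 0.0711). Fisher's exact test lost it at 100 kb and FDR 0.01 (adjusted p = 0.0563). With Fisher's exact test, which ignores neighbours, speckle components (0.0492) and histone genes (0.000702) passed.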

Other observations

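The tests at the DMSO floor, of windows with both means at least 8, of glycolysis against ribosomal protein genes, of shifted windows, and of regions with HIF2 target, glycolysis or ribosomal protein genes taken alone, with and without S6 kinases, were chosen after the results were seen; those of neighbouring residuals and of regions with HIF2 target or glycolysis genes together were written before. Regions with a HIF2 target gene tied to them changed more than the other lower regions. The median change of the lowest-FDR window was -1.36 in 10 such regions and -0.70 in the other 297, by the authors' deposited tables (permutation test, two-sided p = 9e-05, adjusted p = 0.00078 over 26 tests), and the median over all called windows was -1.07 against -0.58 (permutation test, adjusted p = 0.00100). A difference in DMSO means, 10.77 against 10.70, did not pass (permutation test, p = 0.73390). In the lowest-FDR window the PT2399 mean was 6.09 in the region tied to BHLHE40 and 7.96 in that tied to LOXL2. It was at least 8 in 308 of all 314 merged regions. The test was not repeated without the BHLHE40 and LOXL2 regions. For the 28 regions tied to the ribosomal protein list the medians were -0.99 and -0.69 in the lowest-FDR window (permutation test, adjusted p = 0.00283), but 3 of these regions hold an S6 kinase gene and no ribosomal protein gene. Without them the medians were -0.89 in 25 regions and -0.70 in the other 282 (adjusted p = 0.03791), and the difference in the median over called windows, -0.07, did not pass (permutation test, adjusted p = 0.24295). Their DMSO means were higher than those of the others, 10.99 against 10.67 (permutation test, adjusted p = 0.01008), and with the trend on the DMSO mean removed the difference in change was -0.29 (adjusted p = 0.00900). The difference between 9 HIF2 target regions and 24 ribosomal protein regions without the kinases, 1 shared region left out, was -0.38 and did not pass after adjustment (permutation p = 0.04830, adjusted p = 0.07849). With the kinases it was -0.29 against 27 regions (permutation test, adjusted p = 0.14125). All these permutations, and those below, treated regions of 100 to 1560 kb as exchangeable. Longer regions can hold more genes and offer more windows for the lowest FDR. Region length and gene number were not adjusted for, so differences due to them are not excluded.

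Lower regions held many glycolysis genes, of which SLC2A1 is also on the HIF2 target list, and one explanation is that constitutively transcribed genes in general lie in such regions. Ribosomal protein genes were over-represented too, and the share of glycolysis genes listed exceeded theirs by 14.7 percentage points with a 95% interval of -7.58 to 37.3, which treats genes as independent (14.4 points, -8.14 to 37.2, without the S6 kinases), so an excess specific to glycolysis was not shown and the general explanation stays open. The other explanation, that regions with HIF2 target or glycolysis genes fall further than other lower regions, was not decided: the difference of medians was -0.365 for the lowest-FDR window (permutation p = 0.00114) but -0.13 for the median of called windows (p = 0.06470), and -0.32 and -0.13 with the first version of the tie (p = 0.00452 and 0.07735). With the trend on the DMSO mean removed the difference was -0.45 (permutation test, adjusted p = 0.00100); the 7 glycolysis regions alone passed in none of the 3 measures (adjusted p = 0.09983, 0.25738 and 0.17435), while the HIF2 target regions alone did, and the difference between these 2 groups was not tested. An effect of HIF-2α inhibition and one of PT2399 on active regions at large remain possible and were not told apart.

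Windows higher with PT2399 outnumbered lower ones. A DMSO mean at its lowest value accounts for 90.6% of the higher calls, which is what a subtraction or scaling that empties the DMSO windows would give; whether the floor is technical was not tested, since no value per library or antibody was used. It does not account for all higher calls, since 554 higher windows had both means of at least 8, beside 358 lower ones. Part of these 554 calls rested on the adjustment shared with the other windows. With p-values adjusted again over the windows with both means of at least 8 alone, 123 were higher and 247 lower. Over all windows with both means above their lowest value 309 were higher and 227 lower. A flatter PT2399 profile stays open: over the 5925 windows with both means of at least 8 the SD of the means was 0.80 with DMSO and 0.49 with PT2399. With the trend on mean signal removed, residuals of neighbouring windows that share no sequence had a correlation of 0.43 over 5048 pairs (at most 0.0486 in 1000 permutations), but the bound written for that test was wrong, since it removes the trend in question and its windows hold 3.31% of the higher calls. Regional differences between libraries, such as background of the assay, and a redistribution of SON after inhibition both stay open.

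Some windows called lower had a PT2399 mean at its lowest value, 69 of 3425 over the 100 kb tables and 340 of 6686 over the 50 kb tables. If the placement of the window were the cause, a window shifted by 1 step should often have had a mean at least 3 units higher; 20.3% of the 69 and 31.2% of the 340 had one, between the bounds set for and against. On chromosome 7 the 50 kb window starting at 61915001 had means of -0.05 with DMSO and 4.40 with PT2399, and that starting at 61920001 had 11.41 and -0.40. No biological explanation was tested, and placement remains an open explanation for these windows.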
